A study of Homo sapiens with 12 samples.

How the data were processed

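RNA was taken from 2 degron-tagged lines of KOLF2.2J induced pluripotent stem cells after DMSO or after 6 h or 24 h of 5-Ad-IAA, and libraries were made with a directional, paired-end RNA kit, per the labels' protocols. The submitters' processing notes name STAR, Salmon, featureCounts and the GRCh38 build, without versions, parameters or annotation release, and the strand setting of the counting is not given in the sources used here. The deposited table of counts per gene holds whole-number reads assigned to genes, not normalized, and was the main input. The deposited table of Salmon gene estimates holds expected counts, which were rounded to whole numbers for an alternative fit. The authors' table of reads not assigned to genes, also counts, was used for the share of reads outside features; per library 82.5% to 84.3% of reads were assigned. Other deposited tables were not used here.

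Gene symbols were matched for 38568 of 38592 gene identifiers, and 93.9% of the genes tested had coordinates in GENCODE 29. Samples were grouped by the labels into 6 groups of 2 libraries, and counts per library ran from 78233397 to 109109477, deep enough that spread between libraries and not counting error limits most genes. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 7.9 to 30.6. This does not tell separate cultures from repeat libraries of 1 culture, and each library was entered as its own replicate because the labels number them so.

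Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's expression filter with the 6 groups, which left 21780, library sizes were scaled by TMM, and all 12 libraries entered a fit with a mean per group, leaving 6 residual degrees of freedom (prior degrees of freedom 11.1, common biological coefficient of variation 0.0795). Quasi-likelihood F-tests gave log2 fold changes, and the SE was taken as the size of the log2 fold change divided by the square root of F. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. There were 9 comparisons: auxin against DMSO at each time in each line, 24 h against 6 h in each line, the difference of the responses between lines at each time, and DMSO in the RBBP4 line minus DMSO in the CHD1 line. With 2 libraries per group an exact permutation test cannot reach the threshold, so only model p-values are given.

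A set of 40 gene lists, holding 1110 genes of which 1103 were in the table, was fixed before the data were examined; 1 list, of HOX genes, had no tested member. Lists with at least 3 tested members were tested by camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and by fry. Under the estimated correlation 0 lists passed in any of the 9 comparisons, while the preset passed 6 to 17 and fry 5 to 23. At an unadjusted p under 0.05 the estimated correlation passed 0 to 4 lists, and its lowest adjusted p was 0.13. The rule for named genes, also fixed before the data were examined, took the tagged genes and their paralogs, up to 8 largest rises and 8 largest falls per comparison among genes past the threshold with an average log2 CPM of at least 1 and non-overlapping groups, and up to 4 called members of each list, leaving out clone names, pseudogenes and sex-specific genes. HERV-H associated transcripts were listed after the data were examined.

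The tests were tried on simulated counts drawn from the real means and dispersions with 200 genes changed. Of 50 genes changed 4-fold, 96% were called in the simulated RBBP4 comparison with DMSO at 6 h (21780 genes), and of 50 changed 1.25-fold, 12% were. In the simulated CHD1 comparison at 24 h (21780 genes) the shares were 100% and 16%. Unchanged genes made up 3.1% to 6.5% of the calls, and 0 of 39 unchanged lists passed. Genes were drawn independently and lists filled at random, so this says nothing about false calls for lists of genes that vary together. A list shifted as a whole passed camera with an estimated correlation too (adjusted p = 5.7e-04 to 0.0111). As its genes were drawn independently, this does not show how often that test would find a shift in genes that vary together. Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, no count filter, Salmon estimates, fits of only the libraries compared, a replicate block, each library left out in turn, other set tests and, chosen after the data were examined, a per-library trend on exonic length removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.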

Results

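Bulk RNA-seq was measured in KOLF2.2J, an established human induced pluripotent stem cell line that carries a plant-derived auxin receptor, AtOsTIR1, at the AAVS safe-harbour locus. In one derived line the auxin-inducible degron was fused to the C-terminus of RBBP4, a histone-binding subunit shared by several chromatin complexes including NuRD and PRC2. In the other it was fused to the C-terminus of CHD1, an ATP-dependent chromatin remodeller associated with transcribed genes. The auxin analogue 5-Ad-IAA marks the tagged protein for degradation, and cells were collected after 6 h or 24 h of it or after DMSO vehicle. Each of the 6 groups held 2 libraries, 12 in all, with 78233397 to 109109477 counts assigned to genes per library. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No untagged line was given the analogue, and the DMSO libraries carry a 24 h time label, so no vehicle library matches the 6 h time.

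Each comparison asks which transcripts differ after loss of the tagged protein was induced. Fold changes are log2 values with standard errors (SE) from edgeR's quasi-likelihood fit, expression is in CPM, counts scaled to the effective library size, as mean ± SD with n = 2, and a gene is said to rise or fall where its Benjamini-Hochberg adjusted p passed 0.05. A rise or fall is relative to the other transcripts of a library, so a change in total RNA per cell would not be seen. Coordinates are from GRCh38 (GENCODE 29). The first principal component of log2 CPM, with 40.2% of the variance, separated the lines, and the next, with 23.9%, set the 6 h libraries apart from the rest in both lines.

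The degron acts on protein, so transcript levels of the tagged genes do not measure depletion. RBBP4 (chromosome 1, 32651142 to 32686211, plus strand) stood at 200 ± 3.84 CPM in DMSO, 212 ± 0.147 at 6 h and 184 ± 8.12 at 24 h in its own tagged line, with log2 fold changes of 0.08 ± 0.08 and -0.12 ± 0.08 (edgeR adjusted p = 0.446 and 0.292). CHD1 (chromosome 5, 98853985 to 98928957, minus strand) stood at 66.6 ± 4.24 CPM in DMSO, 59.8 ± 4.35 at 6 h and 47.5 ± 5.56 at 24 h in its own tagged line. It fell at 24 h with a log2 fold change of -0.49 ± 0.09 (edgeR adjusted p = 0.00152), while the 6 h value of -0.15 ± 0.09 did not pass (edgeR adjusted p = 0.171), although with scaling by library totals alone it was -0.32 (adjusted p = 0.00411). In the RBBP4 line CHD1 mRNA was -0.25 ± 0.09 at 24 h (edgeR adjusted p = 0.0604), which passed in 5 alternatives, among them the Salmon estimates (-0.28, adjusted p = 0.0413) and DESeq2 (-0.26, adjusted p = 0.0442). The difference between lines in the 24 h response of CHD1 mRNA did not pass (0.24 ± 0.13, adjusted p = 0.226), although without CHD1 24 h replicate 1 it did (0.36, adjusted p = 0.05). CHD1 mRNA was also lower in the DMSO libraries of the CHD1 line than in those of the RBBP4 line, where it was 121 ± 3.69 CPM. RBBP4 mRNA was likewise lower in DMSO in its own tagged line than in the CHD1 line, where it was 260 ± 7.48 CPM (RBBP4 minus CHD1 line -0.38 ± 0.08, edgeR adjusted p = 0.00141). In the CHD1 line RBBP4 mRNA rose at 6 h (0.21 ± 0.08, edgeR adjusted p = 0.0347), but not with library totals alone (0.04, adjusted p = 0.613). Of the close paralogs, CHD2 fell in all 4 comparisons with DMSO, by 0.52, 0.41, 0.55 and 0.31 on the log2 scale for RBBP4 6 h, RBBP4 24 h, CHD1 6 h and CHD1 24 h. The values for the CHD1 line were weaker in other fits. Once a trend on transcript length was removed the CHD2 values there were -0.15 at 6 h and 0.04 at 24 h, and neither passed. The CHD2 value at 24 h in the CHD1 line also did not pass without DMSO replicate 2 (-0.23), without 24 h replicate 2 (-0.25) or in a fit of only the libraries compared (-0.27). RBBP7, the paralog of RBBP4, did not pass in any of the 4 comparisons, although its CHD1 6 h value of 0.14 became 0.28 and passed with the length trend removed.

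After 6 h of auxin in the RBBP4 line, mitotic transcripts fell and transcripts of DNA replication rose. Of 57 tested G2/M and mitosis genes, which are targets of the DREAM repressor, 45 fell and 0 rose (47 and 0 adjusted over the list alone), with a median log2 fold change of -0.44. CENPA, the centromeric histone H3 variant, fell by 1.7, the mitotic kinases AURKA and PLK1 by 1.19 and 1.17, and the proliferation marker MKI67 by 1.15 on the log2 scale. The list passed limma's camera test with adjusted p = 1.9e-14, but not with adjusted p = 0.527 with an estimated correlation. Of 55 G1/S and DNA replication genes, 32 rose and 1 fell (34 and 1 adjusted over the list alone), among them the GINS subunit GINS3 with 1.07 ± 0.1, CCNE2 with 1.05 ± 0.18, the ribonucleotide reductase subunit RRM2 with 0.99 ± 0.11 and the helicase subunit MCM5 with 0.76 ± 0.11. For that list camera gave adjusted p = 1.3e-06, and adjusted p = 0.98 with an estimated correlation. Of 14 aryl hydrocarbon receptor (AHR) and NRF2 response genes, 12 rose and 0 fell (13 and 1 adjusted over the list alone). The AHR target CYP1A1 rose by 3.17 ± 0.24, the heme oxygenase HMOX1 by 1.7 ± 0.12 and TIPARP by 1.36 ± 0.1 on the log2 scale. Camera gave this list adjusted p = 3.8e-06, and adjusted p = 0.527 with an estimated correlation.

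The largest rises at 6 h in the RBBP4 line included metal-binding metallothioneins. MT1H, MT1G, MT1E, MT2A and MT1F rose by 6.58 ± 0.7, 6.12 ± 0.62, 5.92 ± 0.71, 4.11 ± 0.59 and 3.9 ± 0.47 on the log2 scale, from 0.449 ± 0.188 to 31.6 ± 10.1 CPM in the case of MT1G. These near-identical family members share sequence, so how reads were divided among them is uncertain. DHRS2, a short-chain dehydrogenase (chromosome 14, 23630115 to 23645639, plus strand), rose from 6.23 ± 0.889 to 140 ± 7.91 CPM, and the synaptic adhesion gene LRRTM3 from 0.466 ± 0.056 to 8.05 ± 0.551. TM4SF18-AS1 (chromosome 3, 149284782 to 149333653, plus strand) rose by 5.53 ± 0.28, but it is annotated as antisense and the strand setting of the counting is not given in the sources used here, so its reads cannot be told from those of overlapping genes. The glutamate transporter SLC1A1 fell from 32.7 ± 0.713 to 6.28 ± 0.0122 CPM, the transferrin receptor TFRC from 280 ± 16.1 to 65.1 ± 3.37, and the secreted factor NDNF from 4.85 ± 0.421 to 0.958 ± 0.071. GJA5, ZFYVE28, ELFN2 and LINC01844 fell by 2.19, 2.17, 2.11 and 2.34 on the log2 scale. MIR302CHG, host of the miR-302 cluster, fell by 2.36, although its value was -0.4 in the Salmon estimates, where it did not pass. Of 21780 genes tested, 3904 rose and 4064 fell, 980 and 982 of them more than 2-fold. The number called dropped from 7968 to 4749 without DMSO replicate 1 and to 4931 without 6 h replicate 2.

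**Figure D1:**
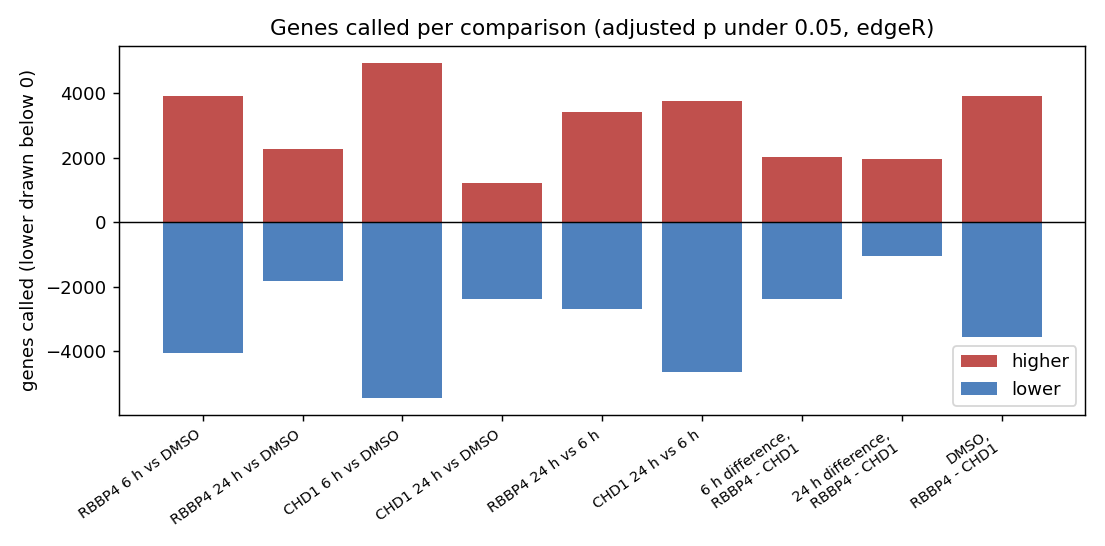
Number of genes called higher (drawn above 0) and lower (drawn below 0) by edgeR in each of the 9 comparisons, each bar a count of genes. The CHD1 line at 6 h had 4948 higher and 5447 lower, and the same line at 24 h 1230 higher and 2386 lower.

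After 24 h in the RBBP4 line mitotic genes were lower, and genes of extraembryonic lineages had risen. Of the 57 G2/M genes, 52 fell and 0 rose (55 and 0 adjusted over the list alone) with a median log2 fold change of -0.63. CENPA fell by 1.88, the mitotic kinesin KIF20A by 1.59, MKI67 by 1.53 and PLK1 by 1.32 on the log2 scale, MKI67 from 350 ± 8.09 to 122 ± 4.42 CPM. Camera gave this list adjusted p = 1.3e-32, and adjusted p = 0.13 with an estimated correlation. Tested directly between 24 h and 6 h, 23 of these genes were lower and 2 higher (camera adjusted p = 1.9e-04, and adjusted p = 0.744 with an estimated correlation). Of 15 trophectoderm and amnion genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone), all at low levels in the examples given here. VTCN1 went from 0.137 ± 0.0152 to 0.939 ± 0.0223 CPM and the transcription factor GATA2 from 0.309 ± 0.0539 to 0.881 ± 0.00679 CPM. For that list camera gave adjusted p = 4.0e-06, and adjusted p = 0.215 with an estimated correlation. Some genes of other lineages rose too: 4 of 14 endoderm genes (0 fell), 4 of 21 mesoderm genes (2 fell) and 3 of 23 neuroectoderm genes (2 fell). None of those lists passed camera with the preset correlation (adjusted p = 0.0775, 0.518 and 0.723). Of 30 targets of the integrated stress response, 1 rose and 14 fell (2 and 15 adjusted over the list alone), STC2 by 0.53 and VLDLR by 0.54 on the log2 scale (camera adjusted p = 3.9e-04, and adjusted p = 0.909 with an estimated correlation). Of the 14 AHR and NRF2 genes 5 rose, CYP1A1 with 3.52 ± 0.24, TIPARP with 1.11 ± 0.1 and the quinone reductase NQO1 with 1.01 ± 0.1 (camera adjusted p = 0.0141, and adjusted p = 0.708 with an estimated correlation). That call was lost in a fit of only the libraries compared (camera adjusted p = 0.0613), and over the 11 alternatives the camera adjusted p ran from 0.00289 to 0.0613.

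The largest changes at 24 h in the RBBP4 line extended several seen at 6 h. DHRS2 reached 263 ± 15.6 CPM, the urea transporter SLC14A2 rose from 0.31 ± 0.0682 to 13.2 ± 0.113 CPM, the fatty acid receptor CD36 from 0.761 ± 0.0337 to 9.56 ± 2.34, the long non-coding RNA BANCR from 1.2 ± 0.015 to 12.7 ± 1.43, and the axonemal dynein DNAH3 from 2.19 ± 0.0567 to 13.9 ± 1.53. WARS2-AS1 and TM4SF18-AS1, both antisense and so uncertain, rose by 3.96 ± 0.12 and 7.14 ± 0.27. TBX10 rose by 2.64 ± 0.17, but its Salmon value was -1.28 and did not pass. The replication-dependent histone genes H2BC12 and H4C8, members of a multigene family whose reads may be shared, rose by 2.6 ± 0.18 and 2.09 ± 0.23. LINC00458, a transcript of pluripotent cells (chromosome 13, 54115783 to 54132866, minus strand), fell from 132 ± 27.6 to 28.9 ± 6.67 CPM, HHLA1 from 12.2 ± 2.71 to 1.75 ± 0.131, and LINC01108 from 10.3 ± 1.43 to 2.8 ± 0.723. HHLA1 fell by 2.79 on the log2 scale here and by 1.62 in the Salmon estimates. ADGRL4, LINC01013 and MVP fell by 1.85, 1.87 and 1.63. In total 2283 genes rose and 1818 fell, 835 and 257 more than 2-fold. The 4101 calls became 1979 without DMSO replicate 1, 2258 without DMSO replicate 2 and 2227 without 24 h replicate 2, and scaling by library totals alone moved the share higher from 55.7% to 66.1%.

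**Figure D2:**
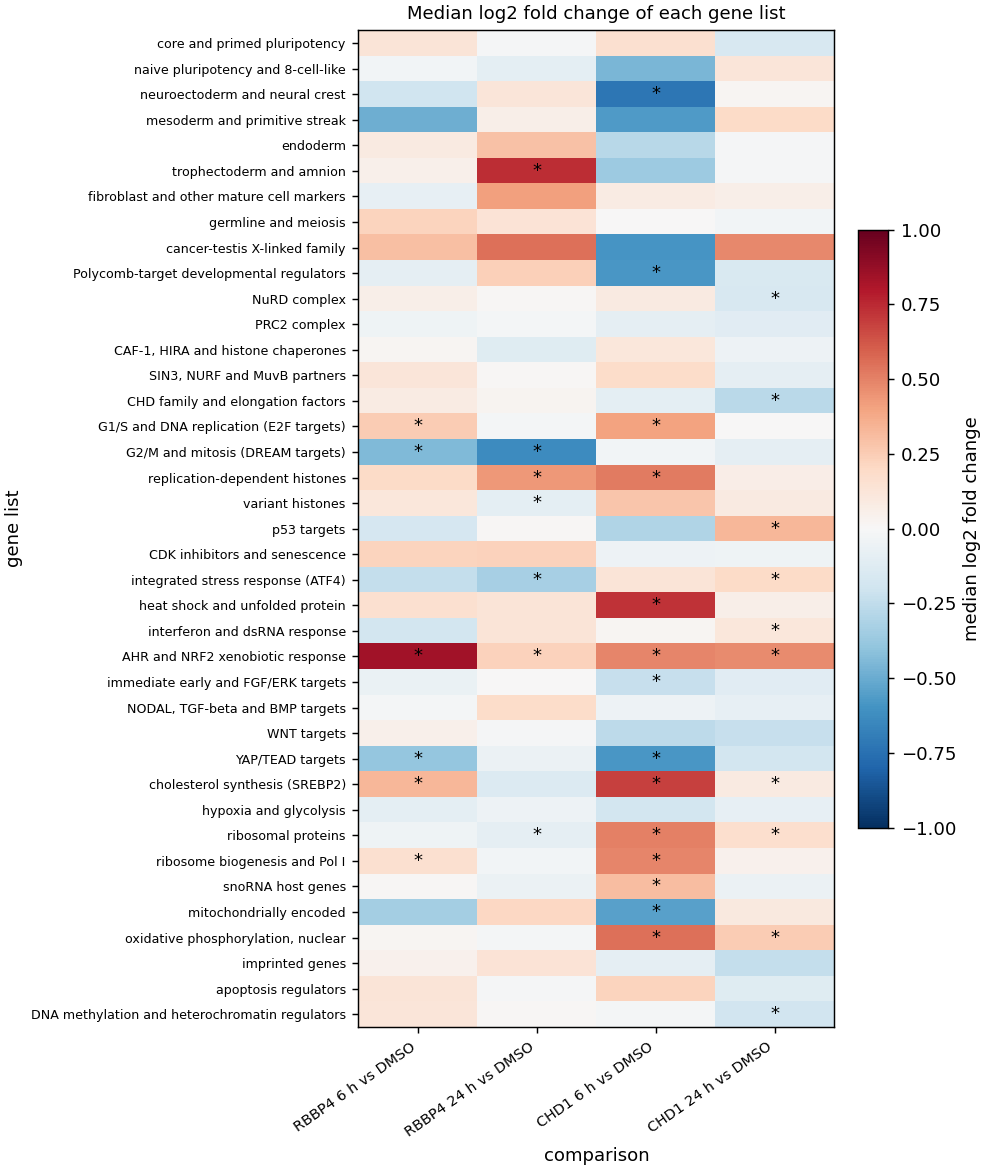
Median log2 fold change of each tested gene list (rows) in the 4 comparisons with DMSO (columns), in colour from -1 to 1, with an asterisk where limma's camera with a preset correlation passed an adjusted p of 0.05. With an estimated correlation 0 lists passed in any of the 4.

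After 6 h in the CHD1 line, most transcripts of ribosomal proteins and of nuclear-encoded oxidative phosphorylation genes rose, while most mitochondrially encoded ones fell. These changes are relative to the other transcripts of a library. The TMM factors were 0.9466 and 0.9277 in these 6 h libraries and 1.065 and 1.036 in DMSO. Of 76 ribosomal protein genes 73 rose and 0 fell (73 and 0 adjusted over the list alone), with a median log2 fold change of 0.5 (FAU 0.76 ± 0.08, RPS3A 0.76 ± 0.13). Camera gave this list adjusted p = 5.4e-17, and adjusted p = 0.5 with an estimated correlation. Of 54 nuclear oxidative phosphorylation genes 48 rose and 0 fell (50 and 1 adjusted over the list alone), such as UQCRQ with 0.99 ± 0.1 and NDUFB2 with 0.9 ± 0.1 (camera adjusted p = 2.5e-14, and adjusted p = 0.5 with an estimated correlation). Of 44 ribosome biogenesis genes 36 rose and 1 fell (36 and 1 adjusted over the list alone), among them the RNA polymerase I factor UBTF with 1.14 ± 0.09 and NOP16 with 1.07 ± 0.11 (camera adjusted p = 4.6e-10, and adjusted p = 0.5 with an estimated correlation). Of 25 cholesterol synthesis genes 22 rose and 0 fell (23 and 0 adjusted over the list alone), MVK by 1.27 ± 0.12 and IDI1 by 1.14 ± 0.11 (camera adjusted p = 2.3e-07, and adjusted p = 0.502 with an estimated correlation). Of 22 heat shock and unfolded protein genes 18 rose and 2 fell (18 and 2 adjusted over the list alone), the chaperone HSPA8 from 1760 ± 255 to 4730 ± 39.9 CPM and DNAJA1 by 1.38 ± 0.11 (camera adjusted p = 3.8e-06, and adjusted p = 0.5 with an estimated correlation). G1/S and replication genes rose in 37 of 55, with 1 lower (37 and 1 adjusted over the list alone), RRM2 by 1.04 ± 0.11 and GINS3 by 0.92 ± 0.11 (camera adjusted p = 1.3e-09, and adjusted p = 0.5 with an estimated correlation). The same libraries had 4.17% ± 0.028 of reads outside annotated features against 5.62% ± 0.19 in DMSO, and 1.83% ± 0.028 of assigned counts from mitochondrially encoded genes against 2.76% ± 0.41.

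Other groups fell at 6 h in the CHD1 line. Of 16 YAP/TEAD targets 1 rose and 11 fell (1 and 11 adjusted over the list alone), ARHGEF17 by 1.3 and TEAD1 by 0.93 on the log2 scale (camera adjusted p = 0.00737, and adjusted p = 0.5 with an estimated correlation). Of 13 mitochondrially encoded genes 9 fell and 0 rose (11 and 0 adjusted over the list alone), MT-ND5 by 0.95 and MT-ND4 by 0.81 (camera adjusted p = 0.0193, and adjusted p = 0.835 with an estimated correlation). That list's camera adjusted p was 0.148 without DMSO replicate 2 and 0.0626 without 6 h replicate 1, and 0.00135 to 0.148 over the 11 alternatives. Of the 14 AHR and NRF2 genes 11 rose and 1 fell (11 and 1 adjusted over the list alone), CYP1A1 by 1.62 ± 0.26, HMOX1 by 1.27 ± 0.12 and NQO1 by 1.08 ± 0.1, while the repressor AHRR fell by 0.97 (camera adjusted p = 0.00128, and adjusted p = 0.5 with an estimated correlation). Single genes with the largest rises were LRAT, the lecithin retinol acyltransferase (chromosome 4, 154626945 to 154753118, plus strand), from 33.2 ± 4.69 to 205 ± 44.9 CPM, the methionine adenosyltransferase MAT2A from 164 ± 5.15 to 623 ± 19.2, UBXN8 from 6.85 ± 0.185 to 27.7 ± 0.421 and the ETS factor SPIB from 8.04 ± 1.71 to 30.8 ± 5.15. TIMP4, SLC27A2 and the homeobox gene HESX1 rose by 1.98 ± 0.22, 1.88 ± 0.13 and 1.82 ± 0.18, and DLEU2, another antisense RNA whose reads cannot be placed, by 2.07 ± 0.24. NPTX1, a neuronal pentraxin (chromosome 17, 80467148 to 80477843, minus strand), fell from 267 ± 31.6 to 22.8 ± 6.42 CPM. NDNF, AHNAK2, FOSB, ADARB2, the Notch ligand DLL1 and PPFIA4 fell by 2.38, 2.31, 2.24, 2.22, 2.2 and 2.14 on the log2 scale, and the lactate transporter SLC16A3 by 2.29, or 1.51 without DMSO replicate 1. In total 4948 genes rose and 5447 fell, 523 and 1539 more than 2-fold. Scaling by library totals alone shifted the median of all genes from -0.055 to -0.219 and the share higher from 47.6% to 30.3%; the ribosomal, oxidative phosphorylation and heat shock lists still passed camera there.

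After 24 h in the CHD1 line fewer genes passed, and targets of p53 rose. Of 32 p53 targets 18 rose and 0 fell (20 and 1 adjusted over the list alone), the growth factor GDF15 by 1.79 ± 0.27, the cell cycle inhibitor CDKN1A by 1.45 ± 0.16 (8.28 ± 0.129 to 22.6 ± 3.81 CPM), PHLDA3 by 0.93 ± 0.12 and FAS by 0.57 ± 0.13. Camera gave that list adjusted p = 2.1e-07, and adjusted p = 0.446 with an estimated correlation. Of the 14 AHR and NRF2 genes 8 rose and 0 fell (8 and 1 adjusted over the list alone), CYP1A1 by 2.26 ± 0.24, TIPARP by 1.46 ± 0.1 and CYP1B1 by 1.42 ± 0.13 (camera adjusted p = 1.5e-05, and adjusted p = 0.445 with an estimated correlation). Of 54 oxidative phosphorylation genes 25 rose and 0 fell (34 and 0 adjusted over the list alone; NDUFB8 0.42 ± 0.09, NDUFA8 0.42 ± 0.08; camera adjusted p = 1.3e-12, and adjusted p = 0.445 with an estimated correlation). Of 76 ribosomal protein genes 19 rose and 1 fell (23 and 1 adjusted over the list alone; FAU 0.45 ± 0.08, RPL11 0.41 ± 0.08; camera adjusted p = 9.6e-10, and adjusted p = 0.778 with an estimated correlation). LRAT remained high at 216 ± 17.2 CPM, the secreted phosphoprotein SPP1 rose from 25.2 ± 0.405 to 84.9 ± 0.251 CPM, and the interferon-induced gene IFIT3 by 1.13 ± 0.19. MT2A and MT1E rose by 2.59 ± 0.48 and 2.54 ± 0.44, but these values rest largely on 24 h replicate 2, without which they were 0.97 and 1.17.

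SNHG3, a host of small nucleolar RNAs (chromosome 1, 28505980 to 28510892, plus strand), fell the most among the genes named for this comparison, from 68.7 ± 3.64 to 18.9 ± 0.26 CPM. The other large falls were in long genes such as NAV3, LUZP2, HECW2, LAMA2, AFF2, CTNND2 and TENM4, by 1.86, 1.7, 1.64, 1.6, 1.59, 1.47 and 1.45 on the log2 scale. CTNND2 spans chromosome 5, 10971840 to 11904043. Among 758 protein-coding genes spanning over 300 kb, 13 rose and 365 fell, and among 3254 of up to 10 kb, 430 rose and 75 fell. At 6 h in the same line the counts were 56 and 418 over 300 kb and 1295 and 484 up to 10 kb. Of 19 genes of the CHD family and elongation factors 8 fell and 0 rose at 24 h (10 and 1 adjusted over the list alone; camera adjusted p = 0.0148, and adjusted p = 0.778 with an estimated correlation). That call was lost with the length trend removed (camera adjusted p = 0.318) and without DMSO replicate 2 (0.0913), the range over the 11 alternatives being 0.00202 to 0.318. In total 1230 genes rose and 2386 fell, 114 and 146 more than 2-fold. The 3616 calls became 2227 without DMSO replicate 2, 1239 without 24 h replicate 2 and 1679 in a fit of only the libraries compared, and removing a trend on transcript length moved the share higher from 34% to 53.1%.

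**Figure D3:**
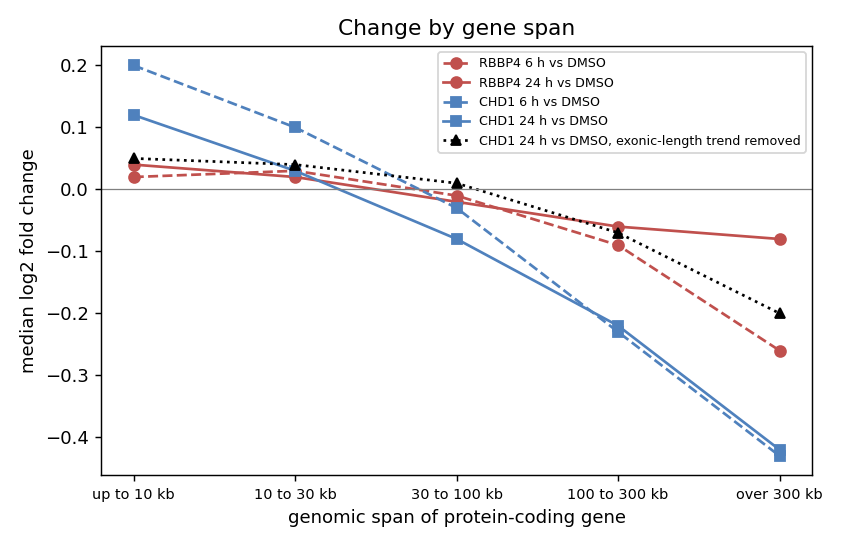
Median log2 fold change (vertical axis) of protein-coding genes in 5 bins of genomic span (horizontal axis), for the 4 comparisons with DMSO and for the CHD1 line at 24 h after a transcript-length trend was removed. In the CHD1 line at 24 h the median was -0.42 over 300 kb and 0.12 up to 10 kb, and -0.2 and 0.05 after the trend was removed.

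**Figure D4:**
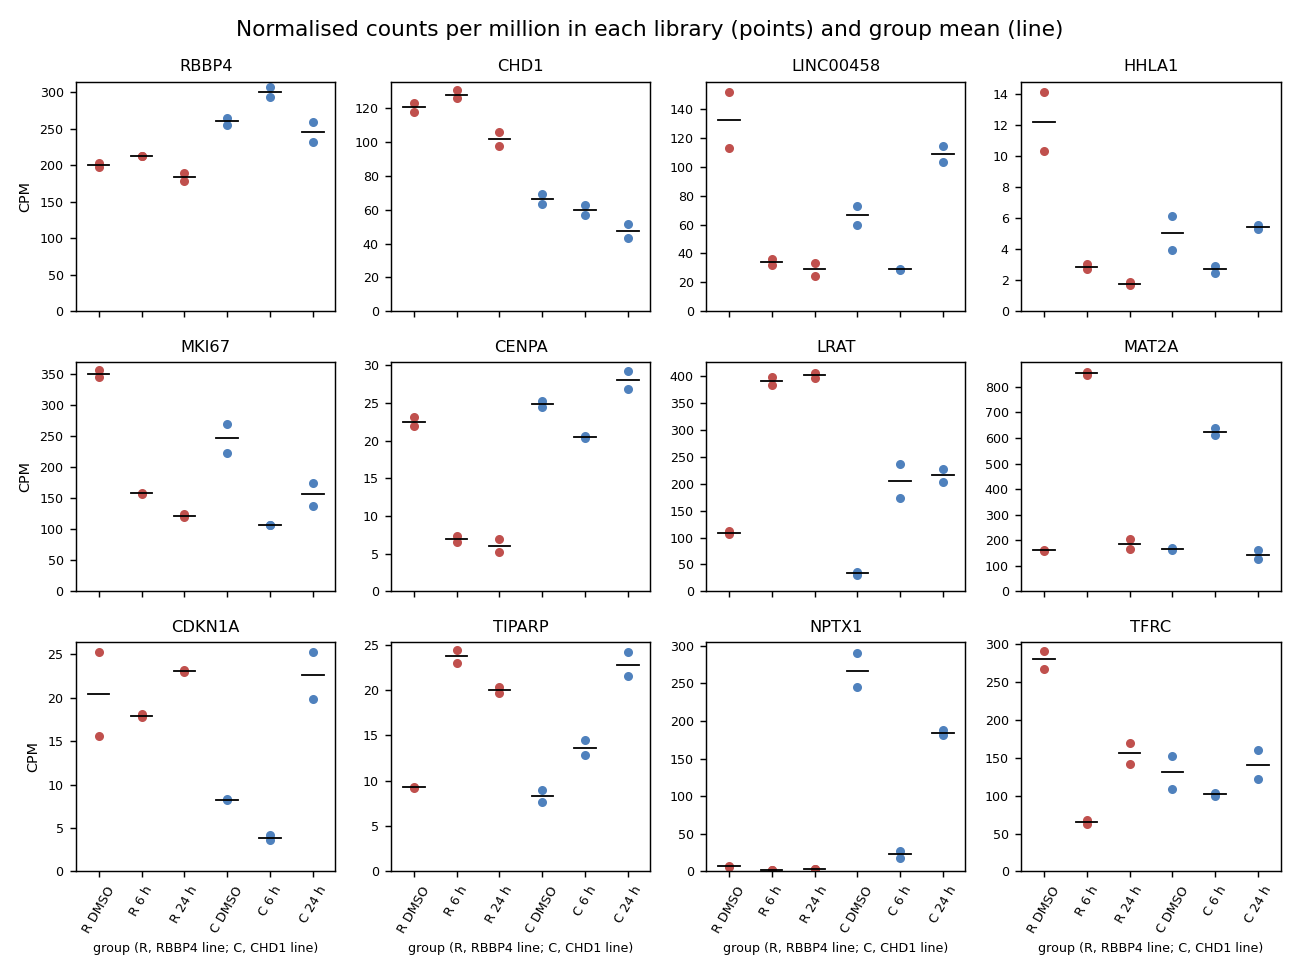
Normalised CPM of 12 named genes in each library (points; red, RBBP4 line, blue, CHD1 line) with the mean of the 2 libraries of a group as a line, on axes that start at 0. CENPA went from 22.5 ± 0.827 CPM in DMSO to 6.07 ± 1.16 CPM at 24 h in the RBBP4 line, and MAT2A from 164 ± 5.15 to 623 ± 19.2 at 6 h in the CHD1 line.

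Between 6 h and 24 h, replication and cholesterol synthesis genes fell in both lines. No vehicle library matches the 6 h time, so a passing response cannot be told apart from handling or medium age at 6 h. In the CHD1 line the cholesterol synthesis list also differed from DMSO at 24 h by camera with the preset correlation, but not with an estimated one. Its median there was 0.04 without DMSO replicate 1 and 0 without 24 h replicate 1. In the RBBP4 line 31 of 55 G1/S genes fell and 0 rose from 6 h to 24 h (36 and 0 adjusted over the list alone; camera adjusted p = 3.9e-10, and adjusted p = 0.744 with an estimated correlation), and 13 of 25 cholesterol synthesis genes fell (camera adjusted p = 1.9e-04, and adjusted p = 0.745 with an estimated correlation). In the CHD1 line 41 of 55 G1/S genes fell (camera adjusted p = 3.5e-11, and adjusted p = 0.535 with an estimated correlation), 18 of 25 cholesterol synthesis genes fell (camera adjusted p = 8.4e-06, and adjusted p = 0.539 with an estimated correlation), 36 of 44 ribosome biogenesis genes fell (camera adjusted p = 2.5e-10, and adjusted p = 0.535 with an estimated correlation), and 20 of 32 p53 targets rose with 3 lower (camera adjusted p = 3.6e-06, and adjusted p = 0.472 with an estimated correlation). UBTF, for example, was 279 ± 19.1 CPM at 6 h and 132 ± 0.68 at 24 h in the CHD1 line. In the RBBP4 line 3410 genes were higher and 2679 lower at 24 h than at 6 h, and in the CHD1 line 3776 and 4646. The 6089 calls in the RBBP4 line became 3468 without 6 h replicate 1, 3231 without 6 h replicate 2 and 3040 without 24 h replicate 1. Scaling by library totals alone moved the share higher in the CHD1 line from 44.8% to 73.6% and the median of all genes from -0.007 to 0.181.

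Changes at 6 h and 24 h were compared within each line. In the RBBP4 line 1175 genes rose and 1201 fell at both times, against 409 and 339 for independent lists, and fold changes correlated across 21780 genes with r = 0.606. In the CHD1 line 872 rose and 1679 fell at both times, against 279 and 597, with r = 0.385. Genes are not independent replicates. Both times share the DMSO libraries, and 20 simulated sets of unchanged groups gave r = 0.482 and 0.463 with at most 0 shared calls. The observed covariances were 0.324 and 0.127, beside simulated ones of 0.0633 and 0.0509. The controls hold 2 libraries per line and were not split between the times, so part of the shared calls and of the covariance may come from sharing them. In the CHD1 line the observed r of 0.385 was below the simulated 0.463. That cannot decide on a shared response, because changes that differ between the times lower r too.

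Responses at the same time were compared between the lines, which share no control libraries. At 6 h 2094 genes rose and 2701 fell in both lines, against 887 and 1020 for independent lists, with odds ratios of 6.09 and 10.8 (Fisher's exact test, two-sided, with p too small to print), and r = 0.503 across genes. HMOX1, GINS3 and RRM2 rose in both lines at 6 h, and NDNF fell in both. At 24 h 219 rose and 461 fell in both, against 129 and 199, with odds ratios of 1.94 and 3.18 (Fisher's exact test, two-sided, p = 1.4e-15 and 3.8e-74) and r = 0.147. As genes are not independent replicates, these p-values do not measure how far the overlap would vary between cultures.

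The difference of the responses was tested directly as RBBP4 minus CHD1. At 6 h 4382 genes differed and at 24 h 3031. The mitotic list differed at both times: of 57 genes 33 were lower in the RBBP4 response at 6 h and 34 at 24 h, with 0 higher (39 and 45 lower adjusted over the list alone), such as UBE2C with -1.27 ± 0.11 and -1.39 ± 0.11. Camera gave it adjusted p = 1.9e-13 and 5.6e-25, with adjusted p = 0.466 and 0.246 with an estimated correlation. Ribosomal protein genes differed in 63 of 76 at 6 h, all lower in the RBBP4 response (camera adjusted p = 2.7e-23, and adjusted p = 0.466 with an estimated correlation). DHRS2 differed by 4.36 ± 0.16 at 6 h and 5.2 ± 0.15 at 24 h, FAM20A by 3.15 ± 0.28 and HPGD by 3.02 ± 0.23 at 24 h, and TFRC by -1.74 ± 0.2 at 6 h. The 4382 calls became 2561 without RBBP4 DMSO replicate 2, 2296 without RBBP4 6 h replicate 1 and 2793 without RBBP4 6 h replicate 2. The 3031 became 1630 and 1688 without RBBP4 DMSO replicate 1 or 2 and 1896 without RBBP4 24 h replicate 2. Scaling by library totals alone moved the share higher at 6 h from 45.9% to 79.2% and the median of all genes from 0.031 to 0.204, and removing the transcript-length trend moved the share at 24 h from 65% to 51.4%. The Salmon estimates gave 51.9% there.

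The DMSO libraries of the lines differed at 7495 genes, 3929 higher and 3566 lower in the RBBP4 line, so each line was compared with its own controls. The labels name a different parental subline of KOLF2.2J for each tagged line, so this comparison and the differences between responses mix the tagged gene with clone and subline. CTSF, a lysosomal protease, stood at 0.158 ± 0.0593 CPM in the RBBP4 line and 26.7 ± 1.99 in the CHD1 line, SDR42E1 at 0.107 ± 0.042 and 12.4 ± 0.782, TRO at 1.04 ± 0.253 and 63.9 ± 1.7, ZNF736 at 0.0198 ± 0.0131 and 10.9 ± 1.11, and NPTX1 at 6.66 ± 1.17 and 267 ± 31.6. The NODAL pathway antagonists CER1 and LEFTY2 were higher in the RBBP4 line, at 9.54 ± 2.99 against 0.578 ± 0.00779 and 26.4 ± 1.72 against 3.9 ± 1.32 CPM, as was the collagen COL12A1. Of 49 replication-dependent histone genes 20 were lower in the RBBP4 line and 0 higher (21 and 0 adjusted over the list alone; camera adjusted p = 3.1e-04, and adjusted p = 0.586 with an estimated correlation). Of 32 p53 targets 13 were higher and 2 lower, CDKN1A by 1.3 ± 0.16 and ZMAT3 by 1.23 ± 0.12 (camera adjusted p = 0.00104, and adjusted p = 0.586 with an estimated correlation). The 7495 calls became 4684 and 4565 without RBBP4 DMSO replicate 1 or 2 and 3842 without CHD1 DMSO replicate 1, and scaling by library totals alone moved the share higher from 52.4% to 33.5% and the median of all genes from -0.026 to -0.137.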

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

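All the tests of explanations here were chosen after the result was seen, except the counts of HERV-H members below 0 in the Salmon estimates and of members not seen falling. Each difference listed first is a response that differed between the lines or between times by a test of the difference itself (edgeR for genes, limma's camera with a preset correlation for lists); with an estimated correlation 0 lists passed, and 2 and 4 did so unadjusted at 6 h and 24 h. Between 24 h and 6 h 6089 genes differed in the RBBP4 line and 8422 in the CHD1 line. The response to auxin differed between the lines at 4382 genes at 6 h and 3031 at 24 h, and of these 331 and 293 were called in opposite directions in the lines.

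At 6 h the lists whose response differed, as the median of RBBP4 minus CHD1 on the log2 scale, were trophectoderm and amnion (0.48), Polycomb-target developmental regulators (0.64), G1/S and DNA replication (-0.12), G2/M and mitosis (-0.44), variant histones (-0.36), integrated stress response (-0.27), heat shock and unfolded protein (-0.41), cholesterol synthesis (-0.34), ribosomal proteins (-0.53), ribosome biogenesis (-0.38), snoRNA host genes (-0.33) and nuclear oxidative phosphorylation (-0.52). With library totals alone 3 of these no longer passed: trophectoderm and amnion (camera adjusted p = 0.0931, range over 15 alternatives 0.0056 to 0.155), Polycomb targets (0.329, range 0.00128 to 0.329) and G1/S (0.394, range 8.5e-04 to 0.394), whose median was then 0.05. In a fit of only the libraries compared the same 3 did not pass (0.0521, 0.0521 and 0.0606), Polycomb targets did not without a count filter (0.0735), and G1/S did not in the Salmon estimates (0.0772) or with the length trend removed (0.125). The integrated stress response did not pass without CHD1 DMSO replicate 1 (0.173, range 8.4e-07 to 0.173). The first 3 also failed with some libraries left out: trophectoderm without RBBP4 DMSO replicate 2 (0.155), RBBP4 6 h replicate 2 (0.0914), CHD1 DMSO replicate 1 (0.0709) or CHD1 6 h replicate 2 (0.0524), Polycomb targets without RBBP4 DMSO replicate 2 (0.0757), CHD1 DMSO replicate 1 (0.199) or CHD1 6 h replicate 2 (0.204), and G1/S without RBBP4 DMSO replicate 2 (0.221), RBBP4 6 h replicate 2 (0.0586), CHD1 DMSO replicate 1 (0.221) or CHD1 6 h replicate 2 (0.199).

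At 24 h they were trophectoderm and amnion (0.44), G2/M and mitosis (-0.58), variant histones (-0.15), p53 targets (-0.27), integrated stress response (-0.42), cholesterol synthesis (-0.25), ribosomal proteins (-0.27), nuclear oxidative phosphorylation (-0.28) and imprinted genes (0.42). Cholesterol synthesis did not pass without RBBP4 24 h replicate 1 (camera adjusted p = 0.185), CHD1 DMSO replicate 1 (0.196) or CHD1 24 h replicate 1 (0.164), with a range of 4.1e-04 to 0.196. Imprinted genes did not pass without RBBP4 24 h replicate 2 (0.0508), CHD1 DMSO replicate 1 (0.0878) or CHD1 24 h replicate 1 (0.141), nor with the length trend removed (0.0862), without a count filter (0.0578), in a fit of only the libraries compared (0.0523) or with a replicate block (0.0521). They passed in 8 of 15 alternatives, with a range of 0.00765 to 0.141.

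Single genes called in opposite directions in the lines, among the largest differences, were TBX10 (2.89), GJA4 (-1.53), ZNF143 (-1.42) and LINC-ROR (-1.38) at 6 h. At 24 h they were FAM20A (3.15), LINC00458 (-2.9), LINC01108 (-2.63), LINC-ROR (-2.49), ABHD12B (-1.92) and HMX2 (-1.78). TBX10 was -0.16 in the Salmon estimates. There the 6 h rise of LINC-ROR in the CHD1 line (0.58, adjusted p = 0.0291) did not pass (0.55, adjusted p = 0.0564), so its opposite call at 6 h was lost.

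Several of these are transcripts associated with the endogenous retrovirus HERV-H, active in pluripotent cells. Of 9 such transcripts listed after the data were examined, 7 fell and 0 rose in the RBBP4 line at 24 h, with a median log2 fold change of -1.05, while in the CHD1 line 5 rose and 1 fell. At 6 h 8 fell and 0 rose in the RBBP4 line, and 6 fell and 2 rose in the CHD1 line. In DMSO 7 of the 9 were higher in the RBBP4 line and 1 lower, with a median of 1.28. If a loss of undifferentiated cells were the cause, the 26 core and primed pluripotency genes should fall alike. Their median was -0.01 (median absolute deviation 0.12), 1.04 above that of HERV-H, with 6 lower and 2 higher. That list was lower at 24 h than at 6 h by camera with the preset correlation. In a fit of only the libraries compared it did not pass (camera adjusted p = 0.0727). The core median argues against such a loss as the whole cause of the large falls, which are in the 5 members chosen after they were seen falling. The other 4 had a median of -0.3, a gap of 0.29, so for them such a loss is argued against less strongly. A partial loss stays open. In the Salmon estimates 9 of 9 lay below 0 and 7 were called lower, as many as in the reported fit. This argues against reads shared among the transcripts that Salmon used as the whole cause. The sources do not name those transcripts, so reads from other repeat copies cannot be judged this way and stay open. Shared reads also stay open as the cause of part of the size of a fall. In the Salmon estimates 1 member fell less by more than 2 standard errors, HHLA1, with -2.79 ± 0.2 against -1.62. Selection of the members stays open: of 4 not seen falling before the test, 2 were called lower at 24 h (ESRG -0.44, LINC00678 -0.47), fewer than the 3 set in advance for that time. At 6 h, for which no number was set, 3 of the 4 were called lower. An effect of the lines' different baselines was not tested.

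Beside these differences the 6 h responses overlapped, with 4795 genes called in the same direction in both lines and a correlation of r = 0.503 across genes. Of these, 403, 8.4%, were called that way in both lines at 24 h as well. That count cannot decide on a constant effect of the auxin analogue, because calls may be lost through low power too. In simulated data with 200 genes changed, 50% to 62% of 1.5-fold changes were recovered per comparison. Far more genes passed in the real comparisons, so power there was not measured. The covariance of fold changes between the lines, which rests on no calls, was 0.287 at 6 h and 0.0453 at 24 h. A constant effect would keep it alike, so the drop argues against that as the main cause, unless other changes at 24 h offset it. For genes that rose at both times a lasting effect stays open. The AHR and NRF2 list passed camera with the preset correlation in both lines at both times, with 12, 5, 11 and 8 of 14 genes higher (RBBP4 6 h and 24 h, CHD1 6 h and 24 h), and CYP1A1 rose by 3.17, 3.52, 1.62 and 2.26. With an estimated correlation none of these list calls passed (camera adjusted p = 0.527, 0.708, 0.5 and 0.445), and in a fit of only the libraries compared the RBBP4 24 h call did not (0.0613). A transient effect of the analogue stays open too, as no untagged line was given it. Handling or medium age that differs between 6 h auxin and DMSO cannot be told apart from the treatment, because there were 0 vehicle libraries at 6 h. A response common to loss of either protein also stays open.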

How the results depend on the processing

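The trend on exonic length was chosen as an alternative after seeing the data; the others were planned. Scaling by RLE factors or library totals, no count filter, Salmon estimates, DESeq2, a replicate block and the length trend each left all 9 counts of called genes within 1.5 times the reported ones. A fit of only the libraries compared did so for 8, the exception being the CHD1 line at 24 h, with 1679. In the RBBP4 line the same fit raised the calls, to 11165 at 6 h, 5342 at 24 h and 8003 between times. In the CHD1 line it lowered them, to 9269 at 6 h and 6642 between times. Replicates differed less in the RBBP4 groups (chi-square per degree of freedom 7.9 to 12.7) than in the CHD1 groups (28.1 to 30.6). The reported fit shares its estimate of spread over all groups. Its counts may therefore be too low for the RBBP4 line and too high for the CHD1 line, though this cause was not tested. The genes called changed more than their number: with the length trend removed 1808 of the 3616 calls in the CHD1 line at 24 h (50%) were made in the same direction, and with library totals alone 68.4% of those for the 6 h difference and 71.9% of those between times in the CHD1 line. The split of calls into higher and lower depended on the setting. With library totals alone the share higher was 66.1% in the RBBP4 line at 24 h, 30.3% in the CHD1 line at 6 h, 73.6% between times in the CHD1 line, 79.2% for the 6 h difference between lines and 33.5% for DMSO, the last 3 on the other side of 50%. The Salmon estimates gave 49% in the RBBP4 line at 24 h, and the length trend gave 53.8% and 53.1% in the CHD1 line at 6 h and 24 h.

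Leaving out 1 library, with the lone library of a group assumed to vary like the other groups, moved 19 of 44 counts beyond 1.5 times. The ranges were 4749 to 5886 (RBBP4, 6 h), 1979 to 2848 (RBBP4, 24 h), 8237 to 9163 (CHD1, 6 h), 1239 to 4399 (CHD1, 24 h), 3040 to 5169 and 6203 to 7746 (24 h against 6 h, RBBP4 and CHD1), 2296 to 4279 and 1630 to 3897 (differences at 6 h and 24 h) and 3842 to 7590 (DMSO). CHD1 at 24 h was lowest without its 24 h replicate 2.

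Among the named genes 7 values that passed in the reported fit or in the alternative changed sign, and the cause was not tested. In the Salmon estimates these were DIABLO (RBBP4 6 h, -0.09) and TBX10 (RBBP4 24 h, -1.28, and 6 h difference, -0.16). With the length trend removed they were LCOR (CHD1 6 h, 0.07) and CHD2 (CHD1 24 h, 0.04, and 6 h difference, -0.3). SIX3 (CHD1 6 h) was 0.16 without CHD1 DMSO replicate 1 and -2.22 without CHD1 6 h replicate 1. Over the named genes and all alternatives 12215 values kept their side of the threshold, 1306 no longer passed and 41 newly passed. Of the values that kept their side, those that passed kept their direction. Direction was not compared for values that passed in neither fit. Of the list calls, 100 were lost with an estimated correlation and 24 with fry.

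Samples share only a replicate number. Replicate differences correlated between groups of a line with r from -0.158 to 0.158 across genes, which gives no sign of pairs; the replicate block called 8278 genes in the RBBP4 line at 6 h and 4157 in the CHD1 line at 24 h. In simulated data, where 200 genes were changed, 50% to 62% of 1.5-fold changes were recovered. Far more genes passed in the real comparisons, which loosens the adjusted threshold, so these shares need not hold there. Real changes of that size may still have been missed.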

Other observations

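The tests of length and GC content here were chosen after the result was seen. In the CHD1 line at 24 h, long genes were lower: across 16033 protein-coding genes the change had a rank correlation of -0.412 with genomic span and -0.469 with exonic length. Genes are not independent replicates. At 6 h the correlations were -0.269 and -0.3. In the RBBP4 line the correlation with span was -0.11 at 6 h and -0.115 at 24 h. Neither was larger in size than the 0.161 and -0.121 between its replicates at these times. Given exonic length the 6 h value was -0.104, beyond the largest between replicates of that line, -0.0841. Given GC it was -0.169, and the largest there was 0.137. Both lay within the largest of all 6 replicate differences, 0.196 and 0.221. In that line 316 genes over 300 kb fell and 78 rose at 6 h (median -0.26). Between the DMSO libraries the correlation with span was 0.275. GC content alone is argued against: given GC, the correlation with span was -0.388, larger in size than in any of the 6 differences between replicates, of which the largest was 0.221. A transcript-length bias between libraries stays open: given exonic length, the correlation with span was -0.17, within the 0.196 seen between the 24 h replicates of the CHD1 line. These replicates differed, with medians of -0.29 and -0.5 for genes over 300 kb. With the exonic-length trend removed, 35 genes over 300 kb rose and 203 fell, and the median was -0.2 in place of -0.42. No biological explanation was tested.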
